A study of Homo sapiens with 2 samples.

How the data were processed

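The series holds 2 libraries of cells labelled as SW1116, 1 infected with a negative control lentivirus and 1 with a lentivirus carrying POLR1D. The label was not checked against a reference profile of the line. Per the labels' protocols, cells positive for the green fluorescent marker were sorted 72 h after infection, total RNA was extracted with Trizol and libraries were made with standard Illumina reagents. The labels put each library in its group. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, nor is whether the libraries keep the strand or how RNA was selected from total RNA.

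Each deposited table lists 20337 features with, per the file headers, a count and an FPKM value. Per the file headers and values, the authors deposited estimated counts that were not normalized, as programs that divide ambiguous reads between features give: 85.3% of them are whole numbers in the control library and 85.5% in the overexpression library, and the rest have decimals. They sum to 12404635 and 13570461. The deposited FPKM values, computed by the authors per kilobase and sequencing depth, are listed as 0.001 for 5172 features in the control library and 5010 in the overexpression library, where the count is 0 or nearly 0. The features are Ensembl genes and 393 assembled loci without an Ensembl identifier, which took 0.325% and 0.324% of the counts. Symbols missing in the tables were filled from GENCODE release 29 by identifier for 1302 features and 184 kept their identifier. In 27 cases a symbol had been turned into a date by a spreadsheet and was replaced from the same annotation by identifier. The tables held 0 columns of other samples.

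For the scaling and the intervals, counts were rounded to whole numbers. Library sizes were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors of 0.909 for the control library and 1.10 for the overexpression library. Log2 ratios are overexpression over control, computed from the unrounded counts scaled to a common library size with 0.5 counts added, for genes with a mean of at least 30 counts over both libraries (11084 genes). The 95% interval of a ratio is the exact Clopper-Pearson interval of the share of a gene's counts in the overexpression library. With 1 library per group no p-value, SD or test of differential expression was computed, and genes are counted by a fixed rule of at least 2-fold. All 2450 higher and all 375 lower genes had counting intervals that exclude a ratio of 1. The floor and the 2-fold rule together fix this, so it adds no support. A count of 3, taken as the limit for a count of 0, corresponds to 0.266 CPM in the control library and 0.201 CPM in the overexpression library. The 10 most abundant genes took 8.16% and 7.03% of the counts.

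The choices that follow were fixed before the data were examined. They are the scale, the floor, the rule of size, 46 gene lists (pathways, complexes, cell types) and the rule for the genes named. That rule takes POLR1D, VEGFA and EREG, the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 100 counts and a regular symbol, up to 3 highest and 3 lowest members of each list, and all subunits of RNA polymerases I and III. Genes named outside this rule are said to be so. For each of 38 lists with at least 5 members past the floor, the median log2 ratio was placed among 10000 random lists of the same size drawn from all genes past the floor within 20 bins of mean expression. The percentile describes these 2 libraries. The other 8 lists are described by their members, where any were among the listed features.

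GC content was brought in only after the data had been seen, when the log2 ratios proved to follow it. The GC content of a gene is the median over its basic protein-coding transcripts in GENCODE release 29 (GRCh38), matched by identifier for 19714 features and for 98.4% of genes past the floor. Several definitions of a gene's GC content were looked at, and the median was kept because its relation with the log2 ratio was the closest of those. Since the definition matters for single genes, the GC content of the principal transcript was used as a second one. A lowess curve with a span of 0.2 was fitted to log2 ratio on GC content and subtracted. The SD across genes was 0.85 before and 0.41 after. Random lists were also matched on 5 bins of expression and 20 of GC content, and on 4, 15 and 4 bins of expression, GC content and transcript length. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 was used, and figures were drawn with matplotlib 3.10.9. DESeq2 1.42.0 supplied size factors for an alternative scaling.

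The steps were tested on simulated counts for this comparison with 200 genes changed. Without a GC trend, of 10907 genes, 100.0% of those simulated at 3-fold and 46.0% of those at exactly 2-fold passed the rule, against 0.009% of unchanged genes. With a simulated GC trend, of 10971 genes, 29.3% of unchanged genes passed the rule without the adjustment and 0.074% with it. Genes simulated at 3-fold passed in 78.0% and 100.0%. The simulation used counting noise only and adjusted with the same GC values that made the trend. In the deposited data the SD was still 0.41 after adjustment, and the GC content of single genes is uncertain. The 0.074% is therefore not the share of false calls among the adjusted genes. Of 200 random null lists, 5% fell outside the middle 95%. They were drawn at random from the same genes as the reference lists, so about this share was set by construction. It does not check lists of related genes or lists that lean to low or high GC content.

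Alternatives were total-count and DESeq2 scaling, no floor and a floor of 300 counts, a pseudocount of 5, a threshold of 1.5-fold, random lists matched on 10 expression bins or none, and, added after seeing the data, both GC adjustments, GC-matched lists and the authors' deposited FPKM values with a pseudocount of 1.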

Results

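RNA was sequenced from cells labelled as SW1116, an established human colorectal cancer line, that had been infected with a lentivirus. The control group had received a negative control virus and the overexpression group a virus carrying POLR1D, the subunit shared by RNA polymerases I and III. Cells positive for the green fluorescent marker were sorted 72 h after infection, and total RNA was sequenced on an Illumina instrument. Each group held 1 library. The control library had a total of 12404635 estimated counts and the overexpression library 13570461. At least 1 count was recorded for 15122 features in the control library and 15303 in the overexpression library, of 20337 listed. The comparison asked how the transcriptome of these cells differed when POLR1D was overexpressed. With 1 library per group it compares these libraries, not the conditions, and none of the differences has a replicate check.

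POLR1D was 45.7-fold higher in the overexpression library, with 44810 counts against 739 in the control library. The log2 ratio was 5.51, with a 95% exact counting interval of 5.41 to 5.62. The authors' FPKM values were 6318 and 83.1. The deposited values do not separate reads of the cells' own gene from those of the POLR1D carried by the virus, so they can hold both. POLR1D took 0.330% of all counts in the overexpression library and 0.006% in the control library. The gene (ENSG00000186184) lies on chromosome 13 at 27620742 to 27744237 on the forward strand, in GENCODE release 29 on GRCh38. All intervals of ratios given here cover counting error only. Reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for that.

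VEGFA, a growth factor for blood vessels, and EREG, a ligand of the EGF receptor, had been chosen before the data were examined, from knowledge of the study's publication. VEGFA had 813 counts in the overexpression library and 715 in the control library, a log2 ratio of −0.22 (−0.37 to −0.07) that became 0.06 when the libraries were scaled by their totals and 0.46 after adjustment for GC content. EREG had 2 counts in the overexpression library and 0 in the control library. Both values are at or under the limit of 3 counts, which corresponds to 0.201 and 0.266 CPM. No fold is therefore given, and a difference was not detectable at this depth. The other 4 ligands of this receptor family past the count floor had between 33 and 163 counts in each library. AREG had 82 against 33 counts and a log2 ratio of 0.90 (0.31 to 1.54), which was −0.06 after GC adjustment and 0.18 with the GC content of its principal transcript alone. TGFA had 141 against 69 counts, with a log2 ratio of 0.62 that was 0.71 after GC adjustment but −0.03 with its principal transcript. NRG1 had 163 against 106 counts, at 0.21 (0.15 after GC adjustment), and HBEGF 156 against 121, at −0.04 (−0.10). Of 18 angiogenesis factors past the floor, 2 were at least 2-fold higher and 2 at least 2-fold lower, with EFNB2 at 1.13 and PGF at −1.24. After GC adjustment EFNB2 was at 0.73 and PGF at −0.43, and 0 of the 18 were past 2-fold either way. With the principal transcript, EFNB2 was at 1.005 and was the only one of the 18 past 2-fold. Their median log2 ratio of −0.22 (−0.06 after GC adjustment) lay at percentile 26.3 of random gene lists with matched expression, and at 94.0 of random lists matched on expression and GC content.

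Across the transcriptome, 2450 of 11084 genes past the floor (22.1%) were at least 2-fold higher in the overexpression library and 375 (3.38%) at least 2-fold lower. After POLR1D, the genes with the highest ratios were PYURF at 3.74 (3.11 to 4.61), with 315.67 against 17.43 counts, and XPO4, a nuclear transport receptor, at 2.40 (1.83 to 3.06). MCM8, a helicase used in DNA repair, followed at 2.22, the kinase TAOK1 at 2.15, SLC35A5 at 2.14 and EFL1, a GTPase that releases EIF6 from the large ribosomal subunit, at 2.12. TVP23B (2.11), CPNE8 (2.07), the spindle protein ASPM (2.06), the ubiquitin ligase MARCH7 (2.05) and the chromatin remodeller HELLS (2.05) completed the 12 highest. CA9, a carbonic anhydrase induced by hypoxia, had the lowest ratio, with 50.01 against 403 counts, 10.6-fold lower in the overexpression library and a log2 ratio of −3.40 (−3.87 to −2.99). NDUFA4L2, another gene induced by hypoxia, was at −1.88 (−2.36 to −1.44) and PPP1R3G, a regulator of glycogen synthesis, at −1.71 (−2.08 to −1.37). The somatostatin receptor gene SSTR5 was at −1.58, the circadian repressor NR1D1 at −1.55, TLE2 at −1.48 and HES6 at −1.47. FAM69B (−1.46), the complement gene C4B (−1.45), the interferon regulator IRF7 (−1.45), CACNA1H (−1.43) and ENTPD2 (−1.42) made up the rest of the 12 lowest. PYURF shares its transcript with PIGY, C4B is nearly identical to C4A, and NR1D1 overlaps THRA on the other strand, so the counts of these genes are uncertain.

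The ratio of a gene followed the GC content of its transcripts. Genes at least 2-fold higher had a median GC content of 41.3% and those at least 2-fold lower 64.7%, against 50.6% over all genes. Spearman's rho between log2 ratio and GC content was −0.889 and Pearson's r −0.869, across 10908 genes, which are not independent replicates. In the lowest of 10 equal classes of GC content (32.0% to 39.9%) the median log2 ratio was 1.33 and 76.4% of genes were at least 2-fold higher. In the highest class (62.7% to 74.7%) it was −0.86, and 23.9% were at least 2-fold lower. A smooth curve on GC content took up 77.2% of the variance of the log2 ratios. Once that curve was subtracted, 134 genes were at least 2-fold higher and 145 at least 2-fold lower. Of the 2450 and 375 genes counted without the adjustment, 108 and 20 stayed past the rule. Scaling by total counts in place of TMM raised all log2 ratios by 0.28 and gave 3407 higher and 80 lower genes. In what follows, the word adjusted marks GC-adjusted log2 ratios, list medians and counts of genes past 2-fold. Counts with the GC content of the principal transcript are added where they differ. POLR1D remained the highest at 4.64 (6.01 with the GC content of its principal transcript alone), followed by PYURF at 3.01. EFL1 was at 1.30, MCM8 at 1.12, XPO4 at 1.08 and TAOK1 at 1.01 (0.93 with the GC content of its principal transcript alone). SLC35A5 (0.85), TVP23B (0.92), CPNE8 (0.82), MARCH7 (0.76), HELLS (0.73) and ASPM (0.72) were under the 2-fold rule after adjustment. CA9 was at −2.75, PPP1R3G at −1.29 and NDUFA4L2 at −1.10, and NR1D1 (−0.93), C4B (−0.90), TLE2 (−0.74) and IRF7 (−0.53) were inside it.

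**Figure D1:**
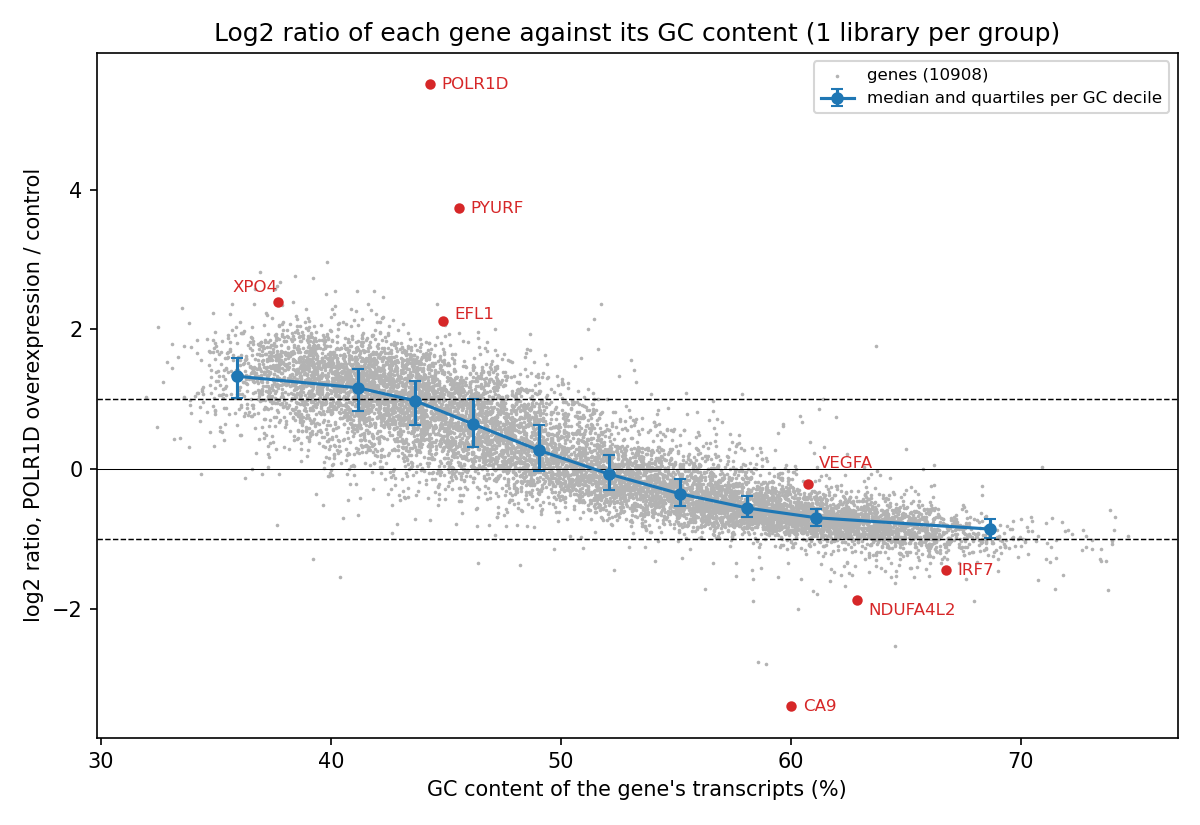
Log2 ratio of overexpression to control (y axis) against the GC content of each gene's transcripts in percent (x axis) for 10908 genes, with the median and quartiles per class in blue and named genes in red; dashed lines mark 2-fold. The medians run from 1.33 in the lowest class to −0.86 in the highest, and POLR1D (5.51), PYURF (3.74) and CA9 (−3.40) stand away from the trend.

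The other subunits of RNA polymerases I and III, which transcribe ribosomal RNA and transfer RNA, did not share the higher level of POLR1D. Of 13 RNA polymerase I subunits past the floor, 2 were at least 2-fold higher, POLR1D itself and TWISTNB at 1.10 (0.63 to 1.61), and 0 were at least 2-fold lower. TWISTNB was at −0.23 after GC adjustment. The largest catalytic subunit POLR1A was at −0.35 (−0.46 to −0.24), POLR1B at 0.85 (0.67 to 1.03) and ZNRD1 at −0.68 (−0.81 to −0.54). Adjusted, they were at −0.24, 0.07 and −0.50. POLR1C, shared with RNA polymerase III, was at −0.24 (−0.41 adjusted) and became 0.03 when scaled by total counts. The median of the list was −0.24 (0.04 adjusted), at percentile 54.9 of random lists matched on expression and 9.95 of those matched on GC content too. Of 18 RNA polymerase III subunits, 3 were at least 2-fold higher, with POLR3F at 1.83 (1.04 to 2.77) and POLR3B at 1.60 (1.14 to 2.11) besides POLR1D. Both were under 2-fold after GC adjustment, at 0.71 and 0.66. The common subunit POLR2E was at −0.62, and at 0.08 after adjustment. The median of this list was −0.01 (0.07 adjusted), at percentiles 69.4 and 30.5. The 7 subunits found only in RNA polymerase II ranged around a median of −0.26 (−0.27 adjusted), with POLR2B at 1.48 (0.34 adjusted) and POLR2I at −0.94 (−0.30 adjusted), at percentiles 62.9 and 29.4.

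**Figure D2:**
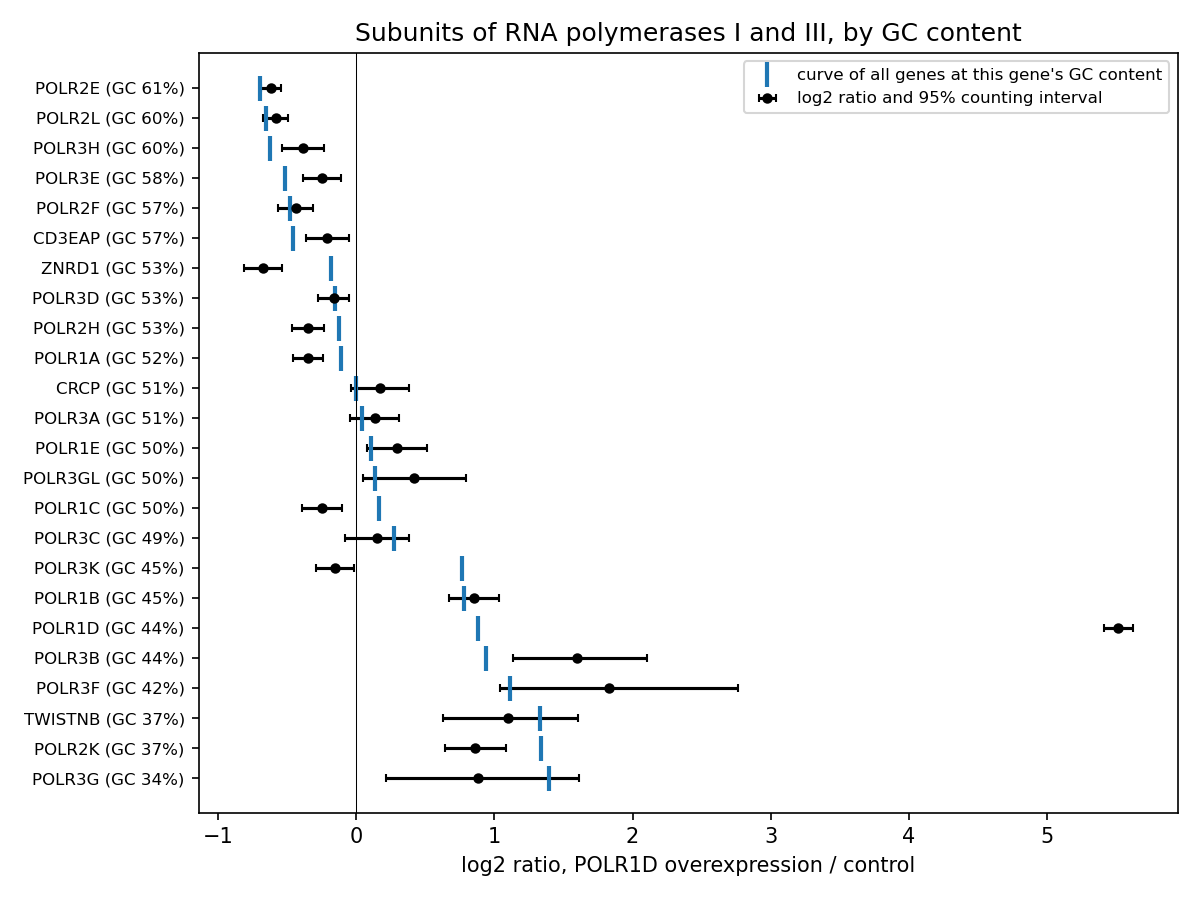
Log2 ratio of overexpression to control (x axis, points with 95% counting intervals) for the subunits of RNA polymerases I and III, ordered by GC content, with the value of the curve of all genes at each GC content as a blue bar. POLR1D at 5.51 lies far above its bar, while the other subunits lie within 1 log2 unit of theirs.

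Ribosome biogenesis factors were higher in the overexpression library than random genes. Of 73, 26 were at least 2-fold higher and 2 at least 2-fold lower, and the median log2 ratio was 0.56 (0.12 adjusted). Adjusted, 0 of the 73 were past 2-fold in either direction. That median lay at percentile 100 of lists matched on expression and 99.5 of lists matched on expression and GC content. UTP15, a factor of the small subunit processome, was at 2.04 (0.77 adjusted) and the kinase RIOK2 at 1.90 (0.58). The 2 lower genes were BOP1 at −1.02 (−0.15) and TBL3 at −1.01 (−0.19). Of 11 transcription factors and cofactors of RNA polymerase I, 5 were at least 2-fold higher, among them the termination factor TTF1 at 1.504 (0.54 adjusted) and the initiation factor RRN3 at 1.31 (0.31 adjusted), while UBTF was at −0.33 (0.06 adjusted). Adjusted, 0 of the 11 were past 2-fold. Their median of 0.81 (0.21 adjusted) lay at percentiles 98.1 and 93.6. Of 17 initiation factors and regulators of RNA polymerase III, such as MAF1, 4 were at least 2-fold higher and 0 lower. Adjusted, 1 was at least 2-fold higher (0 with the principal transcript). The 17 had a median of 0.03 (−0.05 adjusted), at percentiles 52.4 and 75.9. GTF3C3 was at 1.91 (0.63 adjusted), MAF1 at −0.89 (−0.13 adjusted) and SNAPC2 at −0.92 (−0.11 adjusted).

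Aminoacyl-tRNA synthetases, which charge tRNAs for translation, were also higher than random genes. Of 20, 6 were at least 2-fold higher and the median was 0.47 (0.16 adjusted), at percentile 99.98 of lists matched on expression and 99.5 of lists matched on GC content too. NARS was at 1.80 (0.92 adjusted) and TARS at 1.78 (0.93), while FARSA and VARS were at −0.91 and −0.92 (−0.20 and −0.15 adjusted). Adjusted, 2 of the 20 were at least 2-fold higher, RARS (1.39) and GARS (1.42, named after its value was seen), but neither was with the principal transcript (0.60 and 0.46). Cytosolic ribosomal proteins had ratios closer to 0. Of 79, RPS24 (1.20, adjusted 0.51) and RPL7 (1.18, adjusted 0.22) were at least 2-fold higher and 0 at least 2-fold lower. Their median of −0.15 (−0.25 adjusted), which was above 0 with scaling by total counts, lay at percentile 100 of expression-matched lists but 2.53 of lists matched on GC content too, and 61 of the 79 lay below the GC curve. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 76 mitochondrial ribosomal proteins, 6 were at least 2-fold higher, from MRPL1 at 1.65 (0.38 adjusted) to MRPL54 at −0.97 (−0.28 adjusted). Their median was 0.00 (−0.13 adjusted), at percentiles 94.5 and 20.7. Of 39 translation initiation and elongation factors, 10 were at least 2-fold higher, led by EIF5B at 1.76 (0.50 adjusted), with a median of 0.12 (−0.07 adjusted) at percentiles 100 and 43.1. Adjusted, 0 genes of these 3 lists were at least 2-fold higher and 1 of each was lower. With the principal transcript 0 were higher, and 4 cytosolic ribosomal proteins, 1 mitochondrial ribosomal protein and 2 translation factors were lower.

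Genes of mitosis and the G2/M phase were the group with the highest median in the overexpression library. Of 43, 22 were at least 2-fold higher and 0 at least 2-fold lower. The median log2 ratio was 1.24, above the middle 95% of random lists matched on expression and GC content (0.49 to 0.96), and 32 of the 43 lay above the GC curve. After GC adjustment the median was 0.27 and 0 of the 43 were past 2-fold. ASPM was at 2.06, the centromere protein CENPF at 1.98 (0.76 adjusted) and the cytokinesis protein ANLN at 1.83 (0.61). PLK1 and CDC20, regulators of mitotic entry and exit, were at −0.55 and −0.52, and at −0.06 and −0.01 after GC adjustment. DNA replication and G1/S genes had a median of 0.17 (−0.10 adjusted), at percentiles 98.9 and 57.6. Of 43 in this group, 8 were at least 2-fold higher, such as CCNE2 (1.78, adjusted 0.44) and RRM1 (1.60, adjusted 0.68), and 2 lower, POLD1 (−1.08, adjusted −0.22) and CDT1 (−1.004, adjusted −0.15). Adjusted, 0 of these 43 were past 2-fold. Replication-dependent histone genes, expressed in S phase, were lower than random genes. Of 20 past the floor, 2 were at least 2-fold lower, HIST1H1E at −1.08 (−1.76 to −0.44) and HIST2H2AA3 at −1.05 (−1.22 to −0.88), and 0 at least 2-fold higher. Adjusted, they were at −0.43 and −0.32, and 1 other gene was past 2-fold lower. HIST1H2AG was at 0.61 (0.05 adjusted). Their median was −0.34 (−0.36 adjusted), at percentiles 0.73 and 0.40. Histone genes are close copies of each other and most of their transcripts lack a poly(A) tail, so their counts are uncertain and depend on how the RNA was selected.

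Genes induced by hypoxia went both ways. Of 33, 7 were at least 2-fold higher and CA9 was at least 2-fold lower. The collagen-modifying enzymes P4HA1 and PLOD2 were at 1.63 and 1.62 (0.46 and 0.29 adjusted), and LOX at 1.36 (1.08, or 0.15 with the GC content of its principal transcript alone). EGLN3, a prolyl hydroxylase acting on hypoxia-inducible factor, was at −0.81 (−1.27 adjusted). Adjusted, 1 was at least 2-fold higher (0 with the principal transcript) and 3 lower. The median of the list was −0.22 (0.02 adjusted), at percentiles 17.6 and 3.62, but at 1.755 and so outside the middle 95% when transcript length was matched too. Of 21 glycolysis genes, 3 were at least 2-fold higher, such as LDHB at 1.53 (0.74 adjusted), and SLC2A1 was at −0.72 (−0.34 adjusted). Adjusted, 0 were at least 2-fold higher and 1 lower. Their median of −0.50 (−0.05 adjusted) lay at percentile 30.8 of expression-matched lists and 1.55 of lists matched on GC content too. Of 56 nuclear genes of oxidative phosphorylation, 4 were at least 2-fold higher, led by NDUFS1 at 1.498 (0.57 adjusted), and 2 lower, with ATP5D at −1.10 (−0.09 adjusted). Adjusted, 0 were past 2-fold, while 4 were at least 2-fold lower with the principal transcript. Their median was −0.19 (−0.20 adjusted), at percentile 98.9 of expression-matched lists and 0.28 of lists matched on GC content too, and 45 of the 56 lay below the GC curve. The genes encoded by mitochondrial DNA could not be analysed, since 0 symbols of their fixed list were found among the listed features.

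Heat shock genes and chaperones of the unfolded protein response were above expression-matched random lists. Of 20 heat shock genes, 7 were at least 2-fold higher, with HSP90AA1 at 1.82 (0.92 adjusted) and HSPD1 at 1.53 (0.52). Their median of 0.31 (0.19 adjusted) lay at percentiles 99.98 and 95.5. Of 24 unfolded protein response chaperones, 4 were at least 2-fold higher, such as DNAJC3 at 1.88 (0.70 adjusted), and the median of 0.27 (0.20 adjusted) lay at percentiles 99.7 and 75.7. Proteasome subunits (31 genes, 8 higher, PSMC6 at 1.87 and 0.55 adjusted) had a median of 0.22 (−0.06 adjusted), at percentiles 99.98 and 50.3. Spliceosome genes (36 genes, 3 higher, SF3B1 at 1.56 and 0.52 adjusted) had a median of 0.04 (0.01 adjusted), at percentiles 99.96 and 68.4. The MYC targets outside ribosome biogenesis (31 genes, 4 higher and 1 lower) had a median of −0.20 (−0.14 adjusted), at percentiles 97.7 and 20.5, with TFRC at 1.70 (0.57 adjusted) and TERT at −1.53 (−0.63 adjusted), although its deposited FPKM was 2.07 in both libraries. Adjusted, 0 genes of these 5 lists were at least 2-fold higher, and 1 proteasome subunit and 1 spliceosome gene were lower (1 and 2 with the principal transcript).

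Most stress and signalling lists held both genes at least 2-fold higher and genes at least 2-fold lower. In the cholesterol synthesis, YAP and TGF-beta lists 0 genes were at least 2-fold lower. Of 28 p53 targets, 7 were at least 2-fold higher, led by SESN1 at 1.55 (0.45 adjusted), and 3 lower, SESN2 (−1.12, adjusted −0.50), BBC3 (−1.05, adjusted −0.21) and GDF15 (−1.05, adjusted −0.26), with a median of −0.05 (−0.03 adjusted) at percentiles 31.8 and 48.7. Of 32 interferon response genes, 10 were at least 2-fold higher, such as IFIT3 at 1.71 (0.82 adjusted), and IRF7 was lower, while ISG15 was at −0.89 (−0.05 adjusted), with a median of −0.18 (−0.06 adjusted) at percentiles 12.9 and 16.1. The amino acid response genes of ATF4 (30 genes, 3 higher and 3 lower) ran from ALDH1L2 at 1.65 (0.56 adjusted) to CHAC1 at −1.17 (−0.43 adjusted), at percentiles 55.3 and 91.2. NRF2 targets (21 genes, 4 higher and 1 lower) ran from TXNRD1 at 1.43 (0.54 adjusted) to OSGIN1 at −1.20 (−0.40 adjusted), at percentiles 84.1 and 4.75. Cholesterol synthesis genes (29 genes, 7 higher) had FASN as the lowest at −0.96 (−0.09 adjusted), at percentiles 71.2 and 23.7. Apoptosis regulators (29 genes, 4 higher and 1 lower) lay at percentiles 42.6 and 3.71. NF-kB targets (16 genes) ran from BIRC3 at 1.43 (0.12 adjusted) to BCL3 at −1.03 (−0.08 adjusted), at percentiles 24.3 and 68.4. Of 24 immediate early genes, FOSB (−1.53, and −1.02 adjusted) and FOSL1 (−1.11, adjusted −0.46) were at least 2-fold lower and KLF6 (1.09, adjusted 0.41) at least 2-fold higher, at percentiles 16.1 and 58.5. Output genes of the ERK pathway (16 genes, 1 higher and 2 lower) had a median of −0.36 (−0.24 adjusted), at percentiles 11.4 and 41.4. DUSP6 was at 1.07 (0.91 adjusted, or 0.53 with the principal transcript), and ETV4 at −1.06 (−0.40 adjusted) and FOSL1 were the lower ones. The YAP targets (22 genes, 4 higher) ran from TEAD1 at 1.47 (0.33 adjusted) to FJX1 at −0.96 (−0.15 adjusted), with a median of 0.33 (0.11 adjusted) at percentiles 97.4 and 98.3. TGF-beta targets (20 genes) ran from SKIL at 1.44 (0.14 adjusted) to JUNB at −0.97 (−0.11 adjusted), at percentiles 48.9 and 90.8. Adjusted, 0 genes were past 2-fold in the p53, interferon, ATF4, cholesterol, apoptosis, NF-kB and TGF-beta lists. The adjusted counts were 2 lower NRF2 targets, 1 lower immediate early gene (FOSB), 1 higher and 1 lower ERK output gene and 1 higher YAP target. With the principal transcript the higher ERK output gene, CCND1 (0.50, and 1.001 adjusted), was at 0.41, the higher YAP target was under 2-fold too, and 1 p53 target was at least 2-fold lower.

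Genes of cell identity mostly lay inside the range of random lists. Epithelial genes (14 past the floor, 2 higher and 1 lower) had DSP at 1.08 (0.68 adjusted) and LSR at −1.06 (−0.24 adjusted), at percentiles 4.43 and 77.9. Mesenchymal genes (24, 3 higher) had ITGB1 at 1.55 (0.30 adjusted) and SNAI1 at −0.94 (−0.39 adjusted), at percentiles 26.7 and 20.4. Wnt targets and intestinal stem cell genes (14) had NOTUM as the lowest at −0.87 (0.04 adjusted), at percentiles 5.59 and 64.0, with CCND1 again as the only one past 2-fold adjusted. MHC class I and antigen presentation genes (14) lay at percentiles 12.8 and 12.6. Of markers of other cell types, 7 of 15 fibroblast genes were past the floor (DCN at 1.36 and 0.31 adjusted, percentiles 22.0 and 18.3), 3 of 11 endothelial genes (1 lower) and 1 of 19 immune cell markers, CD68 at −0.64 (−0.28 adjusted). Of intestinal cell types, 4 of 30 enterocyte genes and 3 of 23 goblet and secretory cell genes (1 lower) were past the floor. Of 19 snoRNA host genes, 3 were listed in the files and all 3 were past the floor. None of the 6 interferon genes listed in the files reached the floor.

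Of the 38 lists with at least 5 members past the floor, 13 lay above and 1 below the middle 95% of random lists matched on expression. If each list behaved like a random draw of genes, 1.9 would lie outside. Members of a list can vary together, so a number above 1.9 is not a test against chance. With matching on GC content as well, 4 lay above and 3 below, and with length added 4 above and 4 below, hypoxia response genes being the added list. When adjusted medians were placed among expression-matched lists, 5 lay above and 6 below. The 5 were mitosis, ribosome biogenesis, tRNA synthetases, unfolded protein response chaperones (99.97) and heat shock genes (99.96), of which the last 2 lay inside with GC matching. The 6 were histones, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrial ribosomal proteins (0.07), ERK output genes (0.87) and the subunits of RNA polymerase II alone (2.04), of which all but histones and oxidative phosphorylation lay inside with GC matching. Outside on the same side in all 4 placements (expression, GC content, length and adjusted medians) were mitosis, ribosome biogenesis, tRNA synthetases and, on the lower side, replication-dependent histones. Oxidative phosphorylation was on the lower side in the 3 that take account of GC content but on the upper side with matching on expression alone. Those 3 placements used the same GC value per gene, so they are not separate checks.

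**Figure D3:**
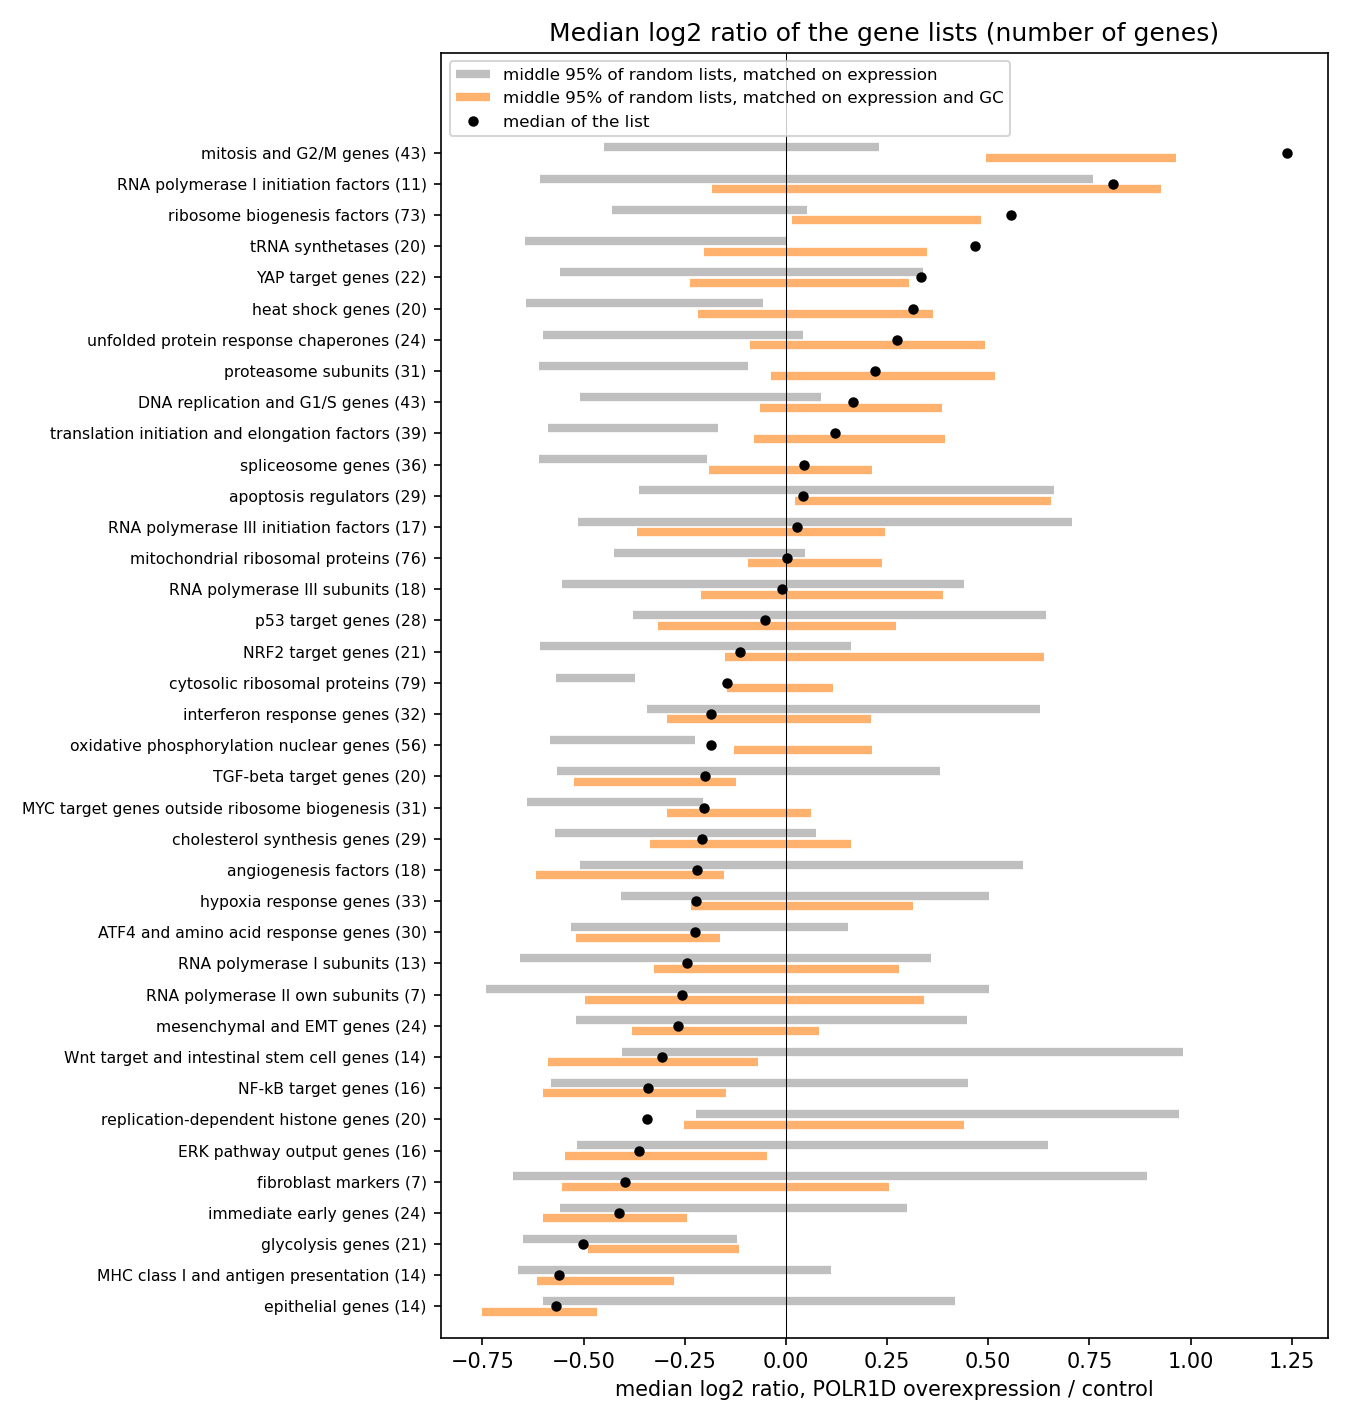
Median log2 ratio of overexpression to control (x axis) of each of 38 gene lists (points, number of genes in brackets), with the middle 95% of 10000 random lists matched on expression (grey) and on expression and GC content (orange). The lists drawn as RNA polymerase I and III initiation factors also hold other factors, such as TTF1 and MAF1. The mitosis median of 1.24 lies right of both bars and the histone median of −0.34 left of both.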

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

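The GC adjustments, the GC-matched lists and the FPKM values were chosen after the data had been seen. The POLR1D log2 ratio stayed far above 0 in all settings. It was 5.79 with total-count scaling, 4.64 and 6.01 after GC adjustment on all transcripts and on the principal transcript, and 6.23 from FPKM. VEGFA turned from −0.22 to 0.056 with total-count scaling and to 0.46 and 0.10 after the GC adjustments. EREG had too few counts for its ratio to be read in any setting. Genes at least 2-fold higher numbered 3926 without a floor, 593 with a floor of 300 counts and 3880 at a 1.5-fold threshold, where the number of genes tested or the threshold itself sets the count, and 134 and 109 after the GC adjustments. Genes at least 2-fold lower numbered 80 with total-count scaling, 1701 without a floor, 173 with the higher floor, 2586 at 1.5-fold, 145 and 177 after the GC adjustments and 103 from FPKM. DESeq2 scaling gave 2335 higher and 450 lower genes. Lists outside the middle 95% of random lists numbered 14 in the main setting, 5 without matching on expression, 7 with matching on expression and GC content, 8 with length added (hypoxia response genes the added one) and 11 after each GC adjustment. Total-count scaling turned POLR1C to 0.032. The GC adjustment turned TWISTNB to −0.23, POLR2E to 0.082, UBTF to 0.059, NOTUM to 0.043 and AREG to −0.063. On the principal transcript TWISTNB was −0.20, UBTF 0.018, CDC20 0.017, NOTUM 0.030 and TGFA −0.027. From FPKM CCND1 was −0.206 and TERT 0.000. HBEGF, whose interval includes 0, was 0.236 with total-count scaling and 0.198 from FPKM. The cause of these shifts across 0 was not tested. The adjusted calls of GARS, RARS, LOX and CCND1 past 2-fold were lost with the principal transcript, and EFNB2 gained one at 1.005. No paired analysis was possible because each group has 1 library, which also rules out leaving out a replicate. Depth limits genes near the floor of 30 counts most.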

Other observations

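The tests on transcript length, on POLR1D acting on a class of transcripts, on mitosis genes with GC matching alone and all 3 on intestinal genes were written down after the result they measure had been seen. The genes first named in this part were also chosen after their values were seen.

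Past 2-fold in the deposited counts and after both GC adjustments were 70 higher and 20 lower genes, of which 19 and 5 had a mean of at least 100 counts. The 5 lower ones were CA9, NDUFA4L2, PPP1R3G, the glycosyltransferase gene B3GALT1 (181.06 against 334.11 counts, log2 ratio −1.29, −2.55 after GC adjustment) and DNASE1 (154.23 against 290.93 counts, −1.32 and −1.06). Among the higher ones besides POLR1D and PYURF were the DNA damage protein TP53BP1 (499.62 against 129.15 counts, 1.54 and 1.10), the anchoring protein AKAP2 (1102 against 376 counts, 1.14 and 1.12) and CMTM4 (313 against 117 counts, 1.01 and 1.73). The length implied by a gene's count and FPKM was 717 bases for POLR1D in the control library and 523 in the overexpression library, a log2 ratio of −0.46, and reads of the cells' own gene and of the viral copy were not separated. The median over 7612 genes was 0.005, and 59 genes (0.775%) were at or below POLR1D.

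Log2 ratios followed GC content between the libraries. Transcript length as the carrier is argued against by its partial rho of 0.153 given GC content (0.132 to 0.171), and codon use alone by a partial rho of −0.486 (−0.504 to −0.468) with the GC content of the 3′ untranslated region given that of the third codon position, across 9704 genes. GC-dependent recovery of fragments during library preparation or sequencing may account for the trend. Subunits of the same complex separated by GC content as other genes did, with a median rho of −0.857 over 4 complexes (range −0.906 to −0.815). That value cannot decide the cause, since any effect that follows transcript GC content would give it too. An effect of POLR1D on GC-poor transcripts as a class cannot be told apart from GC-dependent recovery. The rho of −0.889 comes from the only 2 libraries, 1 per group.

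Mitosis and G2/M genes were higher in the overexpression library. The GC trend, as captured by each gene's GC value, is argued against as the whole cause. The list's percentile was 100 among random lists matched on expression and GC content (middle 95% 0.494 to 0.964). With length matched too it was also 100 (0.557 to 0.948), which argues against length in addition. This list had the highest median of those placed, and its members can vary together, so its percentile is not a test against chance. The match used 1 GC value per gene, not the GC content of the sequenced fragments. A part of the trend that this value misses stays open. The median was 1.24 before and 0.27 after GC adjustment, so most of its size went with the trend. An effect of POLR1D and a difference between the cultures or sorts unrelated to it both stay open with 1 library per group, and neither was tested.

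Genes of the intestinal epithelium were low in both libraries, where 5 of 30 enterocyte genes reached 1 CPM in both (16.7%) and 11 had no count in either, among them CDX1, CDX2, KRT20, FABP1 and SLC26A3. Too few reads is argued against, since 3 counts correspond to 0.266 CPM in the shallower library. Cells of another origin than the label and a loss of intestinal differentiation genes in the labelled line cannot be told apart here, since no reference profile of the line was used. Of 26 general epithelial genes, 16 (61.5%) reached 1 CPM in both libraries, EPCAM among them at only 1.86 and 2.21 CPM. Another 4 had no count in either library, GRHL2, KRT19, OVOL1 and RAB25. CDH1 had 9 counts in the control and 12 in the overexpression library, EPCAM 21 and 33, CEACAM5 1.14 and 1, and KRT19 0 and 0, while KRT8 was at 5056 and 3549 CPM, KRT18 at 2534 and 1821, KRT7 at 1845 and 1198, KRT17 at 3254 and 2145, FOLR1 at 3069 and 1856, CDKN2A at 762 and 465, HOXC10 at 101 and 85.9 and MUC13 at 338 and 553. On the enterocyte list, ALPI (175 and 103 CPM), ANPEP (122 and 77.7) and ALPP (365 and 300.4) went the other way from most members. ALPP is a close copy of ALPI and the 2 can share reads, so they are not separate signs of enterocyte expression.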
